A study of Mus musculus with 4 samples.

How the data were processed

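Gene expression was measured by RNA sequencing in 4 libraries of mouse cells, 2 from a JQ1-sensitive line and 2 from a JQ1-resistant line. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with an Illumina TruSeq RNA kit. The values analysed are the authors' deposited counts, whole numbers of reads per Ensembl gene with no normalization, in a single table of 16591 genes. The submitters' processing notes name FastQC, cutadapt 1.7, TopHat, Bowtie2, HTSeq and limma, and the builds GRCm38 and mm10. The role and order of these tools, the versions of the others, the strand setting of the counting and the annotation release are not given in the sources used here. Every gene in the table had at least 4 counts summed over the libraries, and 558 genes had exactly 4, so genes with fewer counts were absent from the table before any filter was applied here. All 4 columns of the table matched 1 library each by name, and 0 columns were left unused.

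Total counts per library were 13048103 and 10346007 in the sensitive line and 10928239 and 11809635 in the resistant line. A count of 1 in these libraries corresponds to 0.0766 to 0.0967 CPM (counts scaled to a common library total of 1000000), and shares of counts are given with an exact (Clopper-Pearson) 95% interval that covers counting error only. Gene symbols and positions were taken from GENCODE M21, which annotates GRCm38. Of the 16591 identifiers, 16407 matched that release and 184 did not.

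Groups were taken from the titles, with 2 libraries in each. Nothing in the labels says that the replicates came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. Counts were fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) with TMM factors, a model of the group alone, and the filterByExpr filter with a minimum count of 10 and a minimum total of 15. This left 11945 genes. P-values were adjusted by the Benjamini-Hochberg method and a gene was called changed at an adjusted p below 0.05. A second count was limited to changes of at least 2-fold. Standard errors of log2 changes were derived from the quasi-likelihood F statistic. CPM values use library sizes multiplied by the TMM factors and are given as mean and SD over 2 libraries.

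Before the data were examined, 43 gene lists of pathways, B-cell stages, other cell types and cell states were fixed, with 957 symbols, of which 781 were found in the table. The 40 lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The same test was run on 22 chromosomes. With the preset, its p-values rest mainly on the spread between genes, taken as nearly independent, rather than between libraries. An alternative with an estimated correlation rests on the few residual degrees of freedom of 4 libraries and has little power. Its high adjusted p-values, given beside the called lists, therefore do not show that a shift is absent. Members of each list were also counted after adjustment over the list alone. The markers of T cells, with 2 tested members, and of erythroid and NK cells, with 0 each, were too few to test.

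The genes named in the text were chosen by a rule that was also fixed before the data were examined. They are the 12 highest and 12 lowest log2 changes among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, 20 genes of BET signalling, apoptosis, RAS and B cells whatever their result, and up to 4 members of each list with the smallest p. Immunoglobulin genes and predicted genes were left out of the 12 and 12. Of the called genes, 293 were eligible, and 10 immunoglobulin and 26 predicted genes that met the other criteria were not named under that part of the rule. Members beyond the 4 per list, immunoglobulin genes and the genes of the closing section were chosen after their values were seen. The key gene Cdkn2a was not analysed here, and some genes that the rule names are not reported here.

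The scripts were tested on simulated data drawn from the means and library sizes of these libraries for the comparison of resistant against sensitive cells, over 11945 genes with 200 genes changed. Of 50 genes per fold size, 27 were recovered at 1.25-fold, 49 at 1.5-fold, and all 50 at 2-fold and at 4-fold, with 10 false calls. A list moved by 1.3-fold was called and 0 unmoved lists were. Genes were drawn independently of each other, so correlation between list members was absent and its effect on the list test could not be seen. The 1.3-fold move was also larger than the median change of most lists called in the Results. The 200 changed genes were drawn only from genes above a floor of mean CPM, so recovery of weakly expressed genes was not tested.

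Alternatives comprised 3 other scalings (DESeq2's median-of-ratios factors, library size only and upper-quartile factors), 2 other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, leaving out immunoglobulin genes with the 20 genes of most counts, an adjusted p below 0.01, glmTreat against a 1.5-fold change, and for the lists an estimated correlation and fry. A fit without a library leaves its line with a single library, so its p-values rest on the spread of the other line's pair. Calls gained or lost there can come from this change of spread as well as from the library left out. Pairs of libraries were compared by a chi-square test on genes with at least 20 counts summed over the pair. Chi-square over degrees of freedom was 4.10 for the sensitive and 1.80 for the resistant pair, so p-values without a sensitive library rest on the tighter pair. Each pair differed by more than sampling noise, including the pairs within a group, so no library was taken for a copy of another.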

Results

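Counts of RNA sequencing reads were obtained from a JQ1-sensitive and a JQ1-resistant Eμ-Myc cell line, with 2 libraries from each. JQ1 is an inhibitor of the BET bromodomain proteins, which bind acetylated histones and promote transcription, and Eμ-Myc cells are C57BL/6 mouse B-lymphoma cells that express Myc from an immunoglobulin heavy-chain enhancer. The labels describe early-passage cells and name no drug added before harvest. Total counts were 13048103 and 10346007 in the sensitive libraries and 10928239 and 11809635 in the resistant libraries. Across the 11945 tested genes the correlation of log2 CPM was 0.994 between the sensitive libraries, 0.995 between the resistant libraries and 0.988 to 0.989 between lines, where genes are not independent replicates. Mitochondrial transcripts took 5.04% and 5.16% of counts in the sensitive libraries and 4.87% and 4.71% in the resistant libraries.

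The comparison asks which genes differ between a single line that resists a BET inhibitor and a single line that does not. With a single line of each kind, resistance cannot be told apart from any other difference between the lines. Below, resistant and sensitive cells mean these lines. Bcl2, which encodes an inhibitor of apoptosis, rose 6.04-fold in resistant cells, from 18.1 ± 0.22 to 109 ± 5.56 CPM (mean ± SD, n = 2 per line), with a log2 change of 2.59 ± 0.08 (SE) and an adjusted p of 2.13e-12 (edgeR). Plxnc1, a semaphorin receptor, fell from 161 ± 4.12 to 6.60 ± 0.79 CPM, a 24.2-fold difference with a log2 change of -4.60 ± 0.09 and an adjusted p of 9.24e-15. Rbm34, which encodes an RNA-binding protein, rose from 82.1 ± 0.52 to 323 ± 11.2 CPM, and Ebf3, a transcription factor of the early B-cell factor family, from 11.2 ± 1.27 to 50.7 ± 0.33 CPM. On GRCm38, Bcl2 lies on chromosome 1 at 106538178 to 106714274, Plxnc1 on chromosome 10 at 94790866 to 94944835, Rbm34 on chromosome 8 at 126947172 to 126971071 and Ebf3 on chromosome 7 at 137193673 to 137314445.

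Among the other genes with the largest rises were Smim10l1 (log2 change 2.35), Cpeb2, a regulator of mRNA polyadenylation (1.91), Spg20 (1.66), the ubiquitin ligase Rnf213 (1.60), the lactate transporter Slc16a3 (1.42), Tspoap1 (1.23), the pseudokinase Trib2 (1.23), Pcyox1l (1.19) and Trim5 (1.14). Among the largest falls were Bahcc1 (-2.58), the transcription factor Sox13 (-2.53), the intermediate filament gene Nes (-1.63), the ciliary transport gene Ttc21b (-1.36), the arginine deiminase Padi2 (-1.15), Rag1 (-1.09), the growth factor receptor Gfra1 (-1.06), the actin regulator Limk1 (-0.99), Arap2 (-0.94), the amino acid transporter Slc43a1 (-0.91) and Znrd1 (-0.89). Bahcc1 fell from 65.2 ± 6.08 to 10.9 ± 0.22 CPM. The sensitive libraries differed in Slc16a3, at 9.40 and 20.5 CPM, against 38.9 and 38.4 CPM in the resistant libraries. Its log2 change was 0.91 without sensitive replicate 1, and DESeq2 did not call it (adjusted p = 0.304).

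In all, 445 of 11945 genes (3.73%) changed in edgeR, 263 higher and 182 lower in resistant cells, and 117 changed at least 2-fold, 70 higher and 47 lower. The common biological coefficient of variation was 4.38%. In all 445 the libraries of the lines did not overlap, a separation that chance gives to 33.3% of genes and that 47.3% of tested genes showed. DESeq2 called 201 genes, 75 of them at least 2-fold, and the count was 1381 without sensitive replicate 1, 1187 without sensitive replicate 2 and 270 without resistant replicate 2.

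**Figure D1:**
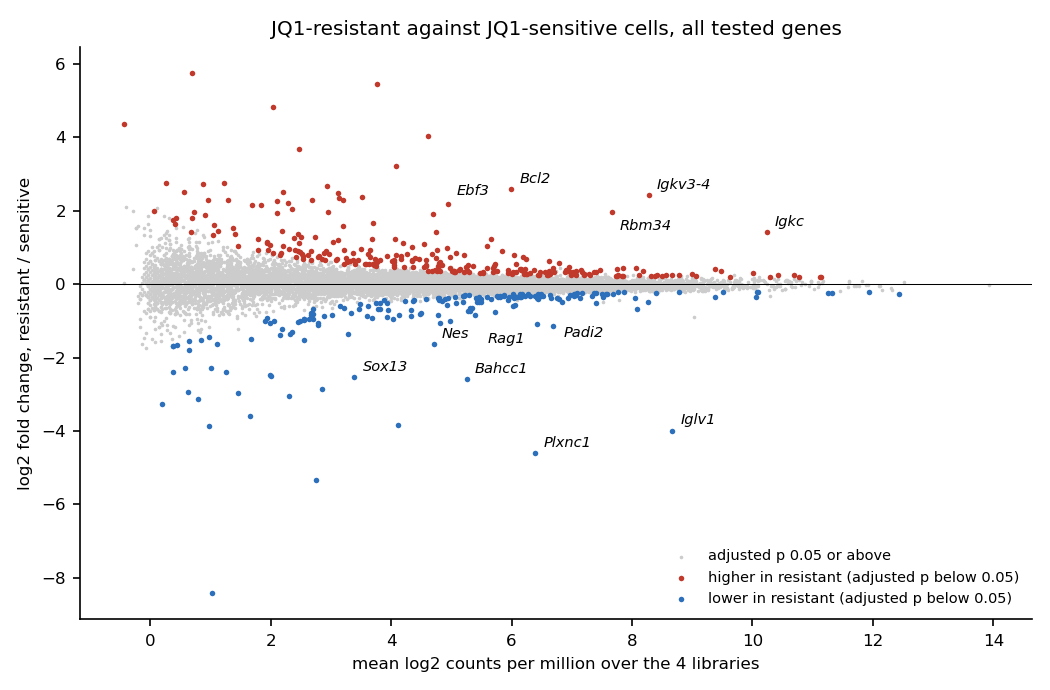
Log2 fold change of resistant over sensitive cells (vertical axis) against mean log2 CPM over the 4 libraries (horizontal axis) for 11945 genes, with genes called higher in red and lower in blue. Bcl2 at 2.59 and Plxnc1 at -4.60 stand apart from genes of similar level.

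Of the 4 tested anti-apoptotic members of the BCL-2 family, Bcl2 rose, Bcl2l2 fell, and Bcl2l1 and Mcl1 did not pass the test. Bcl2l1 (BCL-XL) stood at 13.9 ± 2.81 CPM in sensitive and 11.1 ± 0.52 CPM in resistant cells (log2 change -0.30 ± 0.15, adjusted p = 0.313), and Mcl1 at 259 ± 9.23 and 264 ± 8.55 CPM (0.03 ± 0.06, adjusted p = 0.848). Without sensitive replicate 1 Bcl2l1 was called lower (-0.51), on the spread of the resistant pair alone, and without sensitive replicate 2 its log2 change was -0.10. Bcl2l2 was scarcely expressed, at 1.75 and 0.176 CPM, and DESeq2 did not call it (adjusted p = 0.0589). Among 10 pro-apoptotic members, Bmf (log2 change 0.75) and Bnip3 (0.67) rose and 8 did not pass, among them Bcl2l11, which encodes BIM (0.22 ± 0.08, adjusted p = 0.141), and Bbc3, which encodes PUMA (0.12 ± 0.12, adjusted p = 0.658, or 0.31 and 0.0481 without sensitive replicate 2). Bnip3l (0.26, adjusted p = 0.0581 in edgeR) was called with the replicate block (adjusted p = 0.0139) and with no filter (0.0400). Without sensitive replicate 2 Bnip3l was also called (0.38), on the spread of the resistant pair alone. Adjusted over the list alone, 1 anti-apoptotic member was higher and 1 lower, and 4 pro-apoptotic members were higher and 1 lower. DESeq2 called neither Bmf (adjusted p = 0.0642) nor Bnip3 (adjusted p = 0.900). The log2 change of Bnip3 was 0.32 without sensitive replicate 1 and 1.09 without sensitive replicate 2, and 22.3% of the exonic bases of Bnip3 overlap a gene on the other strand. None of 19 genes of caspases and the apoptosome changed in edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p below 0.05 in edgeR.

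**Figure D2:**
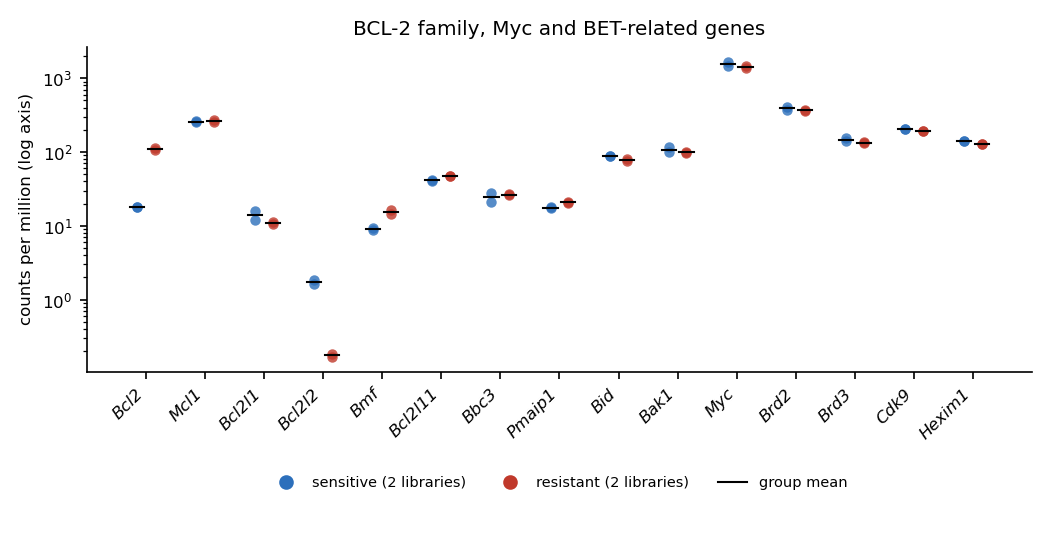
CPM (vertical log axis) of BCL-2 family genes, Myc and BET-related genes in sensitive (blue) and resistant (red) cells, with 1 point per library and a line at the mean of 2 libraries. The points of Bcl2 lie near 18.1 and 109, and those of Mcl1 near 259 and 264.

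The genes of BET proteins and their partners in elongation showed no called change with all 4 libraries and a model of the group alone. Brd2 stood at 389 ± 18.1 CPM in sensitive and 367 ± 11.3 CPM in resistant cells (log2 change -0.08 ± 0.06, adjusted p = 0.514, or -0.13 without sensitive replicate 1 and -0.03 without sensitive replicate 2), and the log2 changes of Brd3 (-0.12), Cdk9 (-0.09) and Hexim1 (-0.12) had adjusted p-values of 0.329 or more. Of 29 BET and elongation genes 0 changed in edgeR, DESeq2 and limma-voom, with 5 at an unadjusted p below 0.05 in edgeR and a camera adjusted p of 0.144. Myc, the driver of these lymphomas, stood at 1558 ± 155 and 1411 ± 44.8 CPM (log2 change -0.14 ± 0.06, adjusted p = 0.250). Without sensitive replicate 1 Myc (-0.24) and Brd3 (-0.19) were called lower, on the spread of the resistant pair alone. Without sensitive replicate 2 the log2 change of Myc was -0.04, and the sensitive libraries stood at 1449 and 1667 CPM of Myc. In the MYC network 1 of 10 genes changed, the MYC antagonist Mxd4, which rose (log2 change 0.54, or 0.34 without sensitive replicate 1), and this count was also 1 adjusted over the list alone. MYC target genes fell as a group by camera (46 genes, median log2 change -0.09, adjusted p = 2.89e-04), with an adjusted p of 0.885 with an estimated correlation. Only 2 of the 46, Nolc1 (-0.21) and Tcof1 (-0.23), both of ribosome production, fell by themselves, and 2 did when adjusted over the list alone. The median difference between the 2 sensitive libraries for this list was -0.09, of the same size as that between the lines, and without sensitive replicate 1 the list's adjusted p was 0.135 and its median -0.05, against -0.14 without sensitive replicate 2. Without resistant replicate 1 and without resistant replicate 2, Nolc1 had adjusted p-values of 0.236 and 0.547 and Tcof1 of 0.312 and 0.388.

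Some genes of antigen presentation rose in resistant cells, 7 of 16 in MHC class I and 2 of 10 in class II. By camera the adjusted p was 7.69e-07 for class I and 1.70e-05 for class II, and both had an adjusted p of 0.738 with an estimated correlation. All 16 class I genes had positive log2 changes, with a median of 0.26. Those that rose included Nlrc5, the transactivator of class I genes (0.83), the peptide transporter Tap1 (0.57), the immunoproteasome subunit Psmb9 (0.52) and the class I heavy chains H2-D1 (0.34) and H2-K1 (0.33). Nlrc5 stood at 13.7 ± 1.41 CPM in sensitive and 24.5 ± 1.33 CPM in resistant cells. The class II genes that rose were the invariant chain Cd74 (0.94, from 18.4 ± 2.60 to 35.5 ± 0.98 CPM) and H2-Ob (0.60), and H2-Ab1 was at 16.9 and 22.7 CPM (0.44, adjusted p = 0.0588, or 2.37e-04 without sensitive replicate 2 and 0.0131 without resistant replicate 2). H2-Aa (2.11, adjusted p = 0.0670) and H2-Eb1 (1.98, adjusted p = 0.0614), near the floor at 0.223 and 0.261 CPM in sensitive and 0.963 and 1.05 CPM in resistant cells, were called with limma-voom (adjusted p = 0.0393 and 0.0402) and with the replicate block (0.0493 and 0.0422). Adjusted over the list alone, 12 class I and 6 class II genes were higher. The calls of Psmb9 with DESeq2 (adjusted p = 0.123), H2-D1 without resistant replicate 1 (adjusted p = 0.0842) and H2-K1 without resistant replicate 2 (adjusted p = 0.0856) were lost. None of 10 interferon-response genes changed in edgeR, DESeq2 or limma-voom, with 5 at an unadjusted p below 0.05 in edgeR, and Ddx58 (0.67, adjusted p = 0.0666) was called with the replicate block (adjusted p = 0.0243) and without sensitive replicate 1 (0.0453).

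Of 21 tested genes of cholesterol biosynthesis 9 rose and 0 fell in edgeR, or 13 rose adjusted over the list alone, and DESeq2 called 1. All 21 had positive log2 changes, with a median of 0.24, and the camera adjusted p was 7.69e-07, or 0.816 with an estimated correlation. The largest rise was that of Stard4, a sterol carrier, from 104 ± 8.42 to 144 ± 5.29 CPM (log2 change 0.47). Msmo1 (0.35) and Sqle (0.30), enzymes of the later steps, and Insig1 (0.28), a sterol sensor, also rose. Sqle had adjusted p-values of 0.108 without resistant replicate 1 and 0.107 without resistant replicate 2, Insig1 of 0.128 and 0.317, and Msmo1 of 0.368 without resistant replicate 2, and the median difference between the sensitive libraries for this list was -0.15.

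Another 3 lists shifted by camera. Ribosomal protein genes rose (median log2 change 0.11 over 30 genes, camera adjusted p = 8.08e-04, adjusted p = 0.885 with an estimated correlation). The 4 members higher were Rps27a (0.30, or 0.19 without sensitive replicate 2), Rpl22 (0.27), Rpl5 (0.21) and Rps3 (0.20), and 12 were higher adjusted over the list alone. Rpl22, Rpl5 and Rps3 lost their calls when either resistant library was left out. Rpl5 and Rps3 also lost theirs with the replicate block, and Rps3 in DESeq2. Xenobiotic metabolism and NRF2 target genes fell (median -0.15 over 17 genes, camera adjusted p = 5.96e-04, adjusted p = 0.816 with an estimated correlation), with 3 members lower, the ferritin heavy chain Fth1 (-0.35), the aldehyde dehydrogenase Aldh1b1 (-0.67) and the thioredoxin reductase Txnrd1 (-0.26), and 6 adjusted over the list alone. Without sensitive replicate 2 the median of this list was -0.09. Mitochondrially encoded RNAs fell (median -0.11 over 15 genes, camera adjusted p = 0.0216, adjusted p = 0.885 with an estimated correlation), with 4 members lower, among them mt-Nd1 (-0.25) and mt-Nd2 (-0.24), and 7 adjusted over the list alone. The median of the mitochondrial list was -0.17 without sensitive replicate 1. Its call was lost without sensitive replicate 2, without resistant replicate 2 and with the replicate block (camera adjusted p = 0.0614). The call was also lost without the 20 genes of most counts and the immunoglobulin genes (camera adjusted p = 0.376), where only 6 of its 15 members were left. Without resistant replicate 2 the adjusted p was 0.224 for mt-Nd1 and 0.364 for mt-Nd2, Txnrd1 had 0.201 without resistant replicate 1 and 0.262 without resistant replicate 2, and DESeq2 gave Aldh1b1 0.0912.

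**Figure D3:**
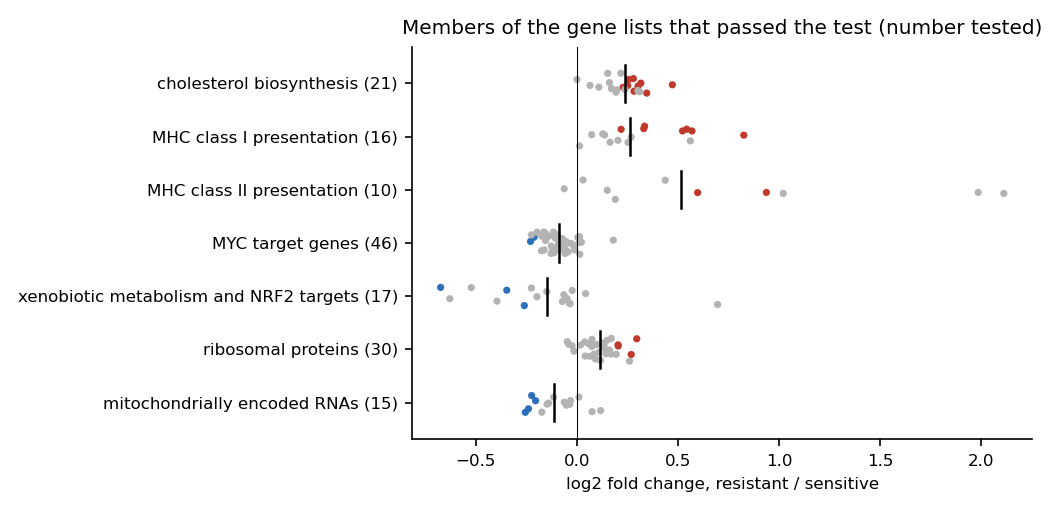
Log2 changes of resistant over sensitive cells (horizontal axis) for the tested members of the 7 gene lists called by camera, with 1 point per gene (called higher in red, called lower in blue, others grey) and a line at the list's median. Medians run from -0.15 for xenobiotic metabolism and NRF2 targets to 0.52 for MHC class II presentation.

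Genes of B-cell stages moved in both directions, and the general B-cell identity genes were expressed in both lines. Ptprc stood at 163 ± 9.57 and 184 ± 7.54 CPM (log2 change 0.17, adjusted p = 0.158, or 0.00131 without sensitive replicate 2), and of 20 identity genes 2 rose, Blk (0.56) and Cd37 (0.22), and 0 fell. Of 17 pro-B and pre-B-cell genes 4 rose and 3 fell. Rag1, the recombinase of antigen receptor genes, fell from 117 ± 1.68 to 54.8 ± 1.13 CPM, the interleukin-7 receptor Il7r fell from 122 ± 6.29 to 93.5 ± 4.82 CPM (log2 change -0.38, adjusted p = 0.00271) and Ccnd3 fell (-0.33), whereas Cd93 rose (0.49). Of 17 mature B-cell genes 4 rose, led by Ms4a1, which encodes CD20 (2.50, from 1.34 ± 0.04 to 7.61 ± 0.76 CPM), and 2 fell, Zbtb32 (-0.86) and Cd38 (-0.40). Adjusted over the list alone, 3 identity genes were higher and 1 lower, 4 pro-B and pre-B genes higher and 4 lower, and 5 mature genes higher and 2 lower. The camera adjusted p-values of these lists were 0.130, 0.22 and 0.421, and on limma-voom values camera called the identity list higher (adjusted p = 0.0294). DESeq2 called neither Blk nor Cd37. Without resistant replicate 1 the adjusted p was 0.0792 for Il7r, 0.0711 for Cd38, 0.0745 for Ccnd3, 0.0521 for Blk and 0.527 for Cd37, and without resistant replicate 2 it was 0.128 for Ccnd3, 0.0689 for Blk and 0.262 for Cd37.

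Plasma-cell genes had 1 member higher, Slpi (0.55), and 1 lower, the plasma-cell surface proteoglycan Sdc1 (-0.70), among 15 tested, with 4 higher and 3 lower adjusted over the list alone. DESeq2 called neither (adjusted p = 0.476 and 0.0529), and Slpi had an adjusted p of 0.198 without resistant replicate 1. Of 25 genes of B-cell receptor signalling 2 rose, the inhibitory phosphatase Ptpn6 (0.36) and the inhibitory receptor Cd22 (0.28), and 2 did adjusted over the list alone. Ptpn6 had an adjusted p of 0.0553 without resistant replicate 1, and Cd22 of 0.215 without resistant replicate 1 and 0.110 without resistant replicate 2. None of 6 germinal-centre genes changed in edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p below 0.05 in edgeR.

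The lines differed in light-chain V counts, beside the same leading heavy-chain V gene. Ighv10-1 took 82.8% and 82.7% of heavy-chain V counts in the sensitive libraries and 82.5% and 82.2% in the resistant libraries. Lambda V genes took 85.6% (95% exact interval 85.0 to 86.2) and 85.1% (84.4 to 85.9) of light-chain V counts in the sensitive libraries, against 7.43% (6.88 to 8.02) and 7.49% (6.96 to 8.04) in the resistant libraries. Iglv1 fell from 766 ± 92.4 to 48.3 ± 0.06 CPM (log2 change -3.99 ± 0.08), and Igkv3-4 rose from 97.0 ± 9.52 to 522 ± 4.07 CPM (2.42 ± 0.07), as did the kappa constant gene Igkc (1.41). Some lambda genes rose as well, the constant gene Iglc2 from 30.3 ± 2.81 to 71.2 ± 2.98 CPM (1.24) and Iglv3 from 4.14 ± 0.36 to 7.10 ± 0.20 CPM (0.77, adjusted p = 0.0239, or 0.499 with DESeq2). The heavy-chain constant gene Ighm stood at 1447 ± 29.0 and 1573 ± 32.0 CPM (0.12, adjusted p = 0.229, or 0.0167 without sensitive replicate 2). Of 34 tested immunoglobulin genes 16 changed, 15 of them at least 2-fold. Igkv3 genes are similar in sequence, so counts for its single members, such as Igkv3-3 (4.04), are uncertain.

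**Figure D4:**
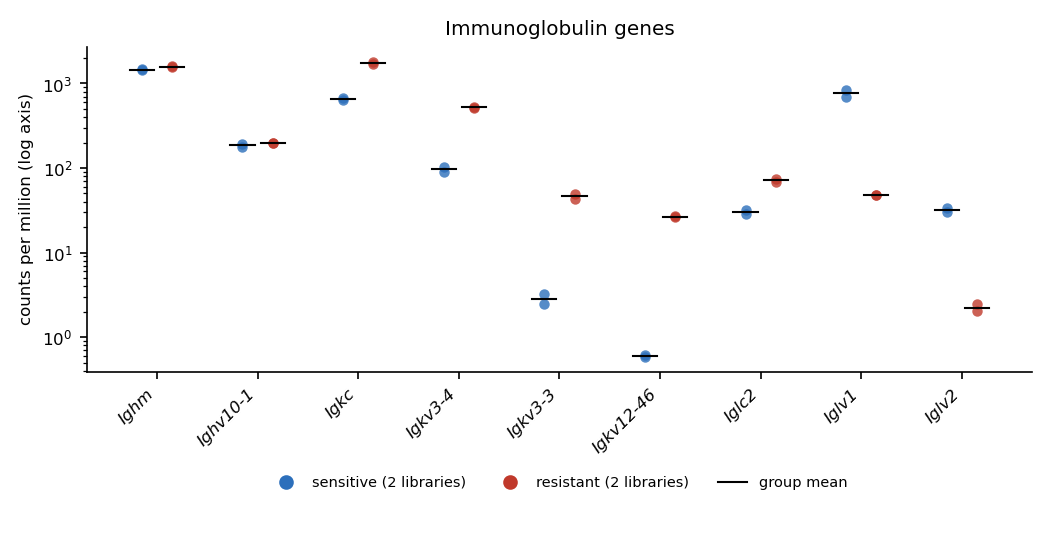
CPM of immunoglobulin genes (vertical log axis) in sensitive (blue) and resistant (red) cells, with 1 point per library and a line at the mean of 2 libraries. Iglv1 moves from 766 to 48.3 and Igkv3-4 from 97.0 to 522, and Ighv10-1 stands at 185 and 198.

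A few output genes of the RAS-MAPK pathway fell. Of 13 output genes 3 fell and 0 rose: Spred2 (-0.85) and Dusp5 (-0.73), both inhibitors within the pathway, and the potassium channel Kcnn4 (-0.44), and 7 were lower adjusted over the list alone, with a camera adjusted p of 0.130, or 0.0168 on limma-voom values. Dusp5 fell from 47.8 ± 2.66 to 28.9 ± 0.35 CPM, and 22.1% of its exonic bases overlap a gene on the other strand. Kcnn4 had an adjusted p of 0.404 in DESeq2 and 0.301 without resistant replicate 2. Dusp6 stood at 1.11 and 1.10 CPM (adjusted p = 0.985). None of 25 pathway components changed in edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p below 0.05 in edgeR, and Nras (-0.08, adjusted p = 0.656, or -0.18 and 0.0456 without sensitive replicate 2) was among them. Of 27 PI3K-AKT-mTOR components 1 rose and 1 fell, the latter being Pik3r5, a regulatory subunit of PI3K gamma (-1.05), with 3 higher and 1 lower adjusted over the list alone.

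Among cell-cycle and p53 genes few changed. Trp53 stood at 236 ± 2.79 and 210 ± 0.85 CPM (log2 change -0.17, adjusted p = 0.125, or 0.0118 without sensitive replicate 1 and 0.0346 without sensitive replicate 2) and its target Cdkn1a at 1.54 and 2.15 CPM (0.51, or 0.22 without sensitive replicate 1 and 0.79 without sensitive replicate 2, adjusted p = 0.452). Of 29 p53 target genes 3 rose, Ddit4 (0.63), Tap1 (0.57), which is also in the class I list, and Trp53inp1 (0.26). Plk3 fell (-0.95, or -1.35 to -0.61 over the alternatives). Adjusted over the list alone, 5 p53 target genes were higher and 1 lower. The camera adjusted p was 0.143, and on limma-voom values camera called the list higher (adjusted p = 0.0266). Of 11 D cyclins and CDK inhibitors Cdkn1b (p27) rose (0.38), Ccnd3 fell (-0.33) and Cdk6 fell (-0.40), with 2 higher and 3 lower adjusted over the list alone. Without resistant replicate 2 the adjusted p was 0.159 for Cdkn1b, 0.128 for Ccnd3, 0.125 for Cdk6, 0.459 for Trp53inp1 and 0.281 for Plk3, and without resistant replicate 1 it was 0.0745 for Ccnd3, 0.207 for Cdk6 and 0.0623 for Trp53inp1. DESeq2 did not call Plk3, Cdk6 or Plk1. Among 30 G2-M genes Plk1 fell (-0.25), with adjusted p-values of 0.188 and 0.368 without resistant replicates 1 and 2. None of 34 G1-S and replication genes and none of 30 oxidative phosphorylation genes changed in edgeR, DESeq2 or limma-voom, with 5 and 2 at an unadjusted p below 0.05 in edgeR.

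Single members of further lists changed. Among 10 ABC transporters the phospholipid exporter Abcb4 rose from 2.96 ± 0.61 to 7.19 ± 0.07 CPM (log2 change 1.26), and Abca2 rose (0.35), with 2 higher adjusted over the list alone. In the glycolysis list 2 of 22 genes rose, Slc16a3 and the glucose transporter Slc2a1 (0.41), with 2 higher adjusted over the list alone. The camera adjusted p of this list was 0.591, and without sensitive replicate 2 it was 0.0241, with a median difference of 0.18 between the sensitive libraries. The deacetylase Hdac9 (0.71) was the single changed gene of 33 chromatin regulators, Nfkbia (0.36) of 17 NF-kB targets, Lig4 (0.32) of 24 DNA damage genes and Ddit4 of 25 genes of the unfolded protein and integrated stress response. Il7r and Il6ra (-0.33) fell among 23 genes of cytokine receptors and JAK-STAT, and Itga4 (-0.22) fell among 19 genes of adhesion and migration, of which 2 rose, S1pr1 (0.42) among them. None of 8 WNT target genes changed in edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p below 0.05 in edgeR. DESeq2 did not call Abca2, Lig4, Il6ra, Itga4, Nfkbia or S1pr1. Without resistant replicate 1 and without resistant replicate 2, adjusted p-values were 0.193 and 0.192 for Abca2, 0.205 and 0.134 for Lig4, 0.138 and 0.141 for Il6ra, 0.319 and 0.502 for Itga4 and 0.259 and 0.219 for Nfkbia, and without resistant replicate 1 it was 0.0745 for S1pr1.

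Of the 2 tested T-cell markers, Cd6 fell from 12.7 ± 0.24 to 0.309 ± 0.08 CPM (log2 change -5.32, adjusted p = 2.27e-09, edgeR), and Cd2 stood at 14.0 ± 0.10 and 15.3 ± 0.65 CPM (0.13, adjusted p = 0.640). None of 5 tested myeloid, 3 stromal and 3 endothelial markers changed in edgeR, DESeq2 or limma-voom, with 0, 1 and 0 at an unadjusted p below 0.05 in edgeR. The stromal marker Vim (-0.22, adjusted p = 0.138 in edgeR) was called lower without sensitive replicate 1 (-0.35), on the spread of the resistant pair alone. Its log2 change was -0.08 without sensitive replicate 2. The 4 tested sex-linked genes likewise had 0 changes in the 3 tools, with 2 at an unadjusted p below 0.05 in edgeR. Of 22 chromosomes 0 shifted by camera, with 2 at an unadjusted p below 0.05, and median log2 changes ran from -0.05 on the mitochondrial chromosome to 0.18 on the Y. The test fry called chromosome 6 (adjusted p = 0.0111), which carries the Igk locus.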

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

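All alternatives in this part were chosen before the data were examined. The other 3 scalings, both other filters and limma-voom gave between 425 and 487 changed genes against 445, and 0 called genes changed sign in any alternative. DESeq2 gave 201 changed genes, all of them among the 445, and 75 of at least 2-fold. An adjusted p below 0.01 left 223, and glmTreat against 1.5-fold called 80. Leaving out a library gave 270 to 1381 changed genes, 110 to 156 of at least 2-fold, 6 to 7 lists and 0 chromosomes. In those fits the lone library of a line is assumed to vary like the pair of the other line, and the sensitive pair differed more (chi-square over degrees of freedom 4.10 against 1.80 for the resistant pair). Without sensitive replicate 1, 663 of 1381 calls were higher, against 263 of 445. With an estimated correlation 0 lists were called (2 at an unadjusted p below 0.05) and with fry 0 (10 at an unadjusted p below 0.05). The estimated-correlation test had little power with 2 libraries per line. Its smallest unadjusted p was 0.0276, for MHC class I presentation, so its lack of calls decides little about the lists. With limma-voom 10 lists were called against 7, the others being pan-B-cell identity, RAS-MAPK output and p53 target genes. 1 chromosome was called by fry and 1 by limma-voom, and the cause was not tested.

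The differences between replicates correlated at -0.020 across genes, so no broad pairing by replicate number was seen. A shared batch limited to some genes would not show in this value and stays open. With the replicate block 595 genes changed, 143 at least 2-fold, with 6 lists and 0 chromosomes called.

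Of the 153 genes followed under alternatives, 108 were called in the main fit. Of these 108, 51 lost their call in some alternative and 57 in none. Of 1972 values of the 153 genes, 1807 stayed called or stayed uncalled, 116 lost a call and 43 gained one. Another 6 changed sign, none of these in a called gene. Over the libraries left out, Bbc3 ran from -0.077 (without sensitive replicate 1) to 0.31, Nras from -0.18 to 0.033 (without sensitive replicate 1), Dusp6 from -0.27 to 0.20 (without resistant replicate 2; 0.036 without sensitive replicate 1) and Mcl1 from -0.0067 (without sensitive replicate 2; -0.0034 without resistant replicate 2) to 0.068. The cause was not tested. The depth and spread limit what can be called, and the smallest simulated changes were recovered in 54% of genes. Those genes all lay above a floor of mean CPM, so the share for weakly expressed genes is not known.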

Other observations

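The genes and gene list of this part and the tests on them were chosen after the result was seen, except the test of library scaling on Bcl2. Several genes of low expression changed by a large factor. Pvr, the homologue of the poliovirus receptor, had 86 counts over the sensitive libraries and 0 over the resistant libraries, at least 28.1-fold lower against a floor of 3 counts over the group. Cd6, a surface receptor of the scavenger family, fell from 12.7 ± 0.24 to 0.309 ± 0.08 CPM (adjusted p = 2.27e-09, edgeR), and Lacc1 rose from 0.261 ± 0.04 to 7.66 ± 0.35 CPM (log2 change 4.84). Bmp4 rose from 0.610 ± 0.10 to 2.99 ± 0.18 CPM and Hadh, a mitochondrial fatty acid enzyme, fell from 12.4 ± 1.24 to 1.71 ± 0.08 CPM.

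Genes known to respond to hypoxia were also higher in resistant cells. Of 25 such genes listed after the values were seen, 22 were tested, and 10 rose and 0 fell: Egln3 (log2 change 2.16), Slc16a3, Ak4 (1.12), Ankrd37 (0.79), Bnip3, Ddit4, Ero1l (0.43), Slc2a1, Kdm3a (0.38) and P4ha1 (0.36). The median log2 change was 0.37, with a camera p of 1.27e-07 and a p of 0.161 with an estimated correlation. Because the list was chosen on these data, its p is no independent evidence. DESeq2 did not call Slc16a3, Bnip3, Ankrd37 or P4ha1, and without resistant replicate 2 the adjusted p was 0.0793 for Kdm3a and 0.318 for P4ha1, and without sensitive replicate 1 the log2 change was 0.91 for Slc16a3, 0.52 for Ankrd37 and 0.32 for Bnip3.

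A candidate explanation for the higher hypoxia genes is a growth state of the dish, such as cell density, rather than a lasting property of the line. The same list differed between the 2 sensitive libraries by a median of 0.198, with 17 of 22 genes higher in sensitive replicate 2, above a limit of 0.0913 taken from the difference between lines, while the resistant libraries differed by a median of 0.0144, below it. With a standard error of 0.118 over genes the value of the sensitive pair decides nothing, and growth state and line cannot be told apart with 2 libraries each, while oxygen sensing was not tested. A shift of all of glycolysis also stays open: 19 of 22 glycolysis genes lay within 0.2 of 0 (camera adjusted p = 0.591), but without sensitive replicate 2 the list was called higher (median 0.14, adjusted p = 0.0241), and it differed by a median of 0.18 between the sensitive libraries. The bound of this test was extended to each library left out after those values had been seen.

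The lambda V counts of the sensitive line and kappa V counts of the resistant line, beside the same heavy-chain V gene, raise the question of mixed cells. The test assumes that mixed-in cells carry all transcripts at the level of their whole line, so a subset of cells with other levels stays open. Under this assumption, resistant cells in the sensitive libraries cannot have supplied all their Igkv3-4. Its ratio of 18.7% was undercut, beyond the 95% exact interval, by 6 of 20 genes at least 4-fold higher in resistant cells, with Igkv3-4 itself counted in the 20. Among the 6 were Igkv12-46 at 2.26% and Lacc1 at 3.36%, but also Igkv3-3 and Igkv3-5, whose counts are uncertain. Under the same assumption, sensitive cells in the resistant libraries cannot have supplied all of the Iglv1 there. Its ratio of 6.24% was undercut by 2 of 12 genes (with Iglv1 itself counted in the 12), Cd6 at 2.41% and Plxnc1 at 4.13%. Smaller shares of mixing remain open. Reads shared among Igkv3 genes leave Iglv1 on another chromosome unmoved, and its log2 change was -3.988. That fall is part of the pattern in question, so whether shared reads raise the counts of Igkv3 genes stays open. As a hypothesis, both lines may descend from cells with 1 heavy chain that differ in light chain, which these counts cannot test, and the lambda constant gene Iglc2 was higher in the resistant line too (1.24).

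The rise of Bcl2 may be specific to the gene rather than to its region or to scaling. The 8 tested genes within 1 Mb had a median log2 change of -0.016, the highest being Gm20302 at 0.40, against 2.59 for Bcl2, so a copy gain of the whole region is argued against, while a gain of the gene alone stays open. The lowest log2 change of Bcl2 over the 3 other scalings was 2.5918. The TMM factors ran only from 0.996 to 1.007, so this test had little room to give another outcome. How the resistant line came to differ, by drug selection or by descent, was not tested.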
